A study of Mus musculus with 37 samples.

How the data were processed

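Polyadenylated RNA from brain of male C57BL/6J mice was measured in 37 libraries. RNA was extracted with the Qiagen RNeasy Mini kit and libraries were made with the ABclonal Fast RNA-seq Lib Prep Kit V2, per the labels. The deposited table holds raw read counts per gene and library, and the submitters' processing notes name STAR 2.7.10a, DESeq2 and the mm10 build. The column names carry the ending of STAR's gene count output. The role of DESeq2, the strand setting and the annotation release are not given in the sources used here. The counts were checked to be whole numbers with a different total in each library.

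The table has 56980 genes, of which 12923 have 0 counts in every library. Symbols came from GENCODE M21, which matched 52073 identifiers, and the 4907 unmatched identifiers hold 3.86% of all counts. Of the matched identifiers, 52036 carry a higher version than in that release, so the annotation used for counting is later than the one used for symbols, and no coordinates are given. Genes that overlap on opposite strands, such as Rbm3 and Rbm3os, can share reads depending on the strand setting.

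Groups were formed from age (adolescent, starting on postnatal day 25, or adult, starting on postnatal day 55), antibiotics or water, and saline or morphine. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalisation, filterByExpr on the 8 groups, which left 19348 genes, and 1 robust quasi-likelihood fit of all 37 libraries with a mean per group. The 9 planned contrasts of 2 groups and 5 planned interactions were tested, with Benjamini-Hochberg adjustment over all genes tested in each and a threshold of 0.05. CPM values use the TMM-scaled totals, except that Drd2, Mbp, Slc17a7 and Ttr of single libraries use the unscaled totals unless stated, and means and SDs cover the 35 libraries with more than 1000000 counts, while all 37 stay in the fit. The totals ranged from 10630727 to 31560468 counts in those 35 libraries. Intervals of single values are not given, since the spread between libraries is the error used.

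Gene lists for cell types, brain regions and pathways (47 lists, all with at least 4 tested members) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists of a contrast. Camera with a correlation estimated from the data was run beside it. Members past the threshold were counted with adjustment over all genes and with adjustment over the list alone.

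Named genes were chosen by a rule. In each contrast of 2 groups it takes, per direction, the 8 genes with the smallest adjusted p and the 7 with the largest change among genes past the threshold with a mean of at least 1 CPM in the higher group. Where fewer than 10 genes passed, it takes all of them and the smallest p values up to 6 genes. It adds up to 4 passing members of each list by smallest p, the genes Fos, Fkbp5, Sgk1, Oprm1, Mbp and Cx3cr1 in every contrast, and up to 6 passing genes of each interaction. Genes with no symbol or a predicted or clone-like name were counted and not named, and the text leaves out some genes by rank from the end. Apart from these, a single gene given by the rule is not reported here. The groups, contrasts, lists, rule, threshold and the settings tried beside the main ones were set before the data were examined.

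The settings set in advance were DESeq2 1.42.0 with its own size factors, edgeR with DESeq2 size factors, no filter on low counts, a fit of only the compared groups, the replicate number as a block, limma-voom with sample weights, leaving out each library in turn, and age averaged over the 4 treatments. Gene lists were also tested with fry. After the data were seen, fits of the 35 libraries over 1000000 counts, of 34 libraries without adolescent water saline replicate 1, and with a term for libraries with more than 20 counts of islet hormone genes were added. Averages of the antibiotic and morphine effects over 4 strata, and 2 further interactions, were also added then. For each contrast the libraries were regrouped into groups of the same sizes and the fit was repeated, over all 56 splits where there were so few, and otherwise over 60 splits drawn for contrasts of 2 groups and 40 for the others, the real one included.

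The procedure was tested on simulated data with 200 changed genes per comparison, shared among several sizes of change. Of the genes with a true change of 2-fold it found 81.8% for age on water with saline, 92.4% for morphine in adolescents on water, 80.3% for morphine in adults on water, 84.8% for antibiotics in adolescents with saline, 84.8% for antibiotics in adults with saline, 87.9% for morphine in adolescents on antibiotics, 89.4% for morphine in adults on antibiotics, 89.4% for antibiotics in adolescents with morphine and 80.3% for antibiotics in adults with morphine. Of those at 1.5-fold it found 55.2% to 73.1% across these comparisons, and of those at 1.25-fold 22.4% to 46.3%. The false share among called genes was 2.4% to 6.34%. The simulated counts were drawn independently for each gene and library, with no outlying library and no shared structure of the samples. The changed genes were taken from those with a mean above 1 CPM. These shares may therefore be better than those in the real data.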

Results

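Polyadenylated RNA from brain was sequenced in 37 libraries from male wild-type C57BL/6J mice. The sample labels name brain as the tissue, and the series title names the medial prefrontal cortex. The mice were adolescent, with treatment starting on postnatal day 25, or adult, with treatment starting on postnatal day 55. They drank water or received antibiotics by mouth, and saline or morphine at 15 mg/kg was injected under the skin for 5 days. These 3 factors gave 8 groups. Adult mice on water with saline had 3 libraries, adolescent mice on antibiotics with saline had 4, and each of the other groups had 5.

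The total per library was 10630727 to 31560468 counts in 35 libraries, with a median of 15910823. Adolescent antibiotics saline replicate 3 held 25165 counts and adult antibiotics morphine replicate 4 held 58764 counts. Both stayed in the fit, whose design was fixed before the data were examined, while means and SDs below come from the 35 libraries with over 1000000 counts. Adolescent water saline replicate 1 stood apart in markers of other brain tissue. Drd2, a dopamine receptor of striatal neurons, was at 55.6 CPM there and at 0.679 to 2.51 CPM in the other 4 libraries of its group. Mbp, a myelin protein, was at 8916 CPM there and at 526 to 1224 CPM in the other 4. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was at 1222 CPM there and at 1740 to 1890 CPM in the other 4. Counts of genes were therefore also taken from 34 libraries, without that library and the 2 near-empty ones, a choice made after seeing the data. Transcripts of pancreatic islet hormones were present in 7 adolescent libraries, with 319 to 735 counts of the insulin gene Ins2. A term for these libraries was tried as a further alternative, also chosen after seeing the data.

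**Figure D1:**
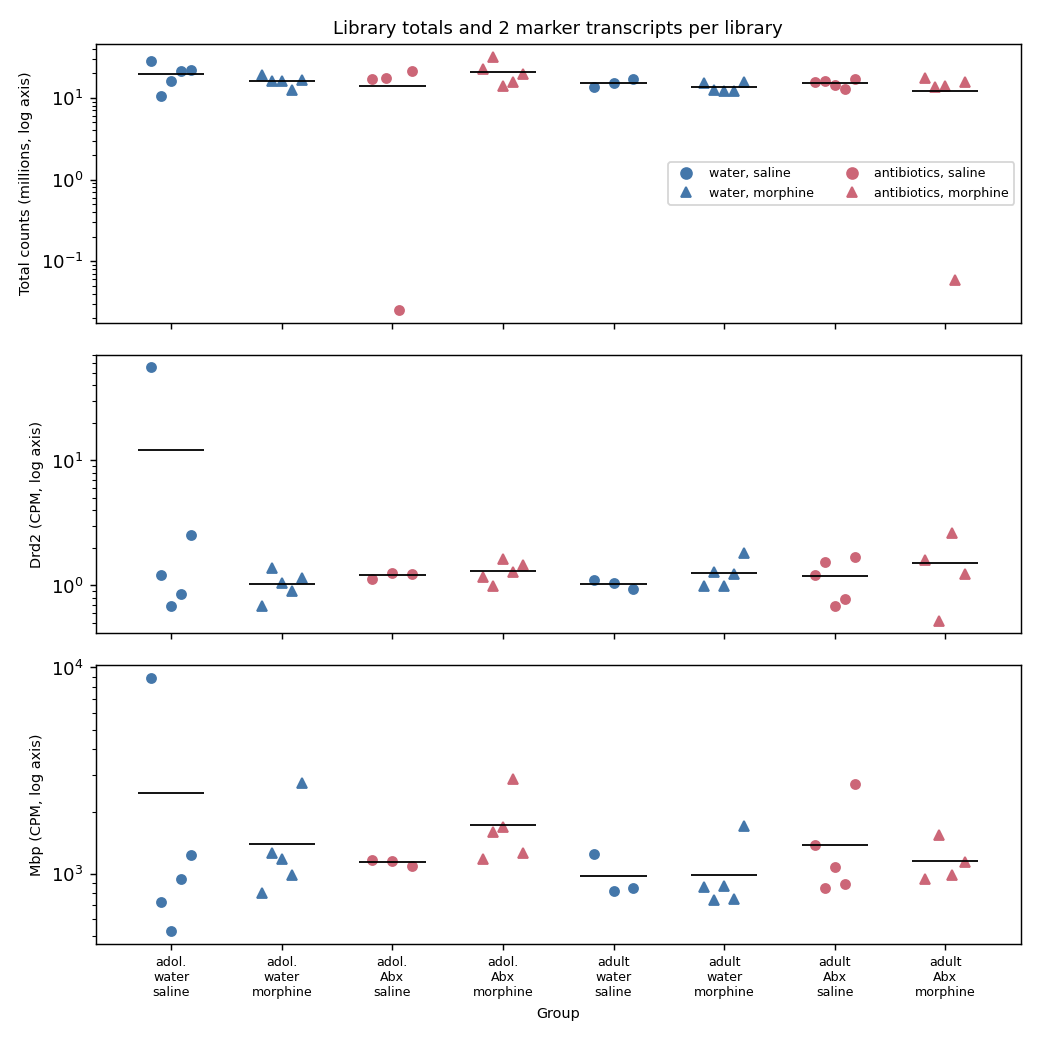
Total counts per library, Drd2 in CPM and Mbp in CPM, all on log axes, for each library of the 8 groups on the horizontal axis, with the horizontal bars at the arithmetic mean of the points drawn. The 2 near-empty libraries lie below 1000000 counts and are left out of the lower panels, and adolescent water saline replicate 1 has the highest Drd2 (55.6 CPM) and Mbp (8916 CPM).

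The first comparison asked how the cortex of adolescent and adult mice differed without antibiotics or morphine. Marcksl1 (ENSMUSG00000047945), which encodes an actin-binding membrane protein of growing neurites, was at 169 ± 19.5 CPM (SD, n = 5) in adolescents and at 65.8 ± 6.98 CPM (SD, n = 3) in adults. Its log2 fold change was -1.35 (SE 0.12, adjusted p = 3.15e-09 in edgeR's quasi-likelihood test). The related gene Marcks fell by 0.41 on the log2 scale, and Gnb4, a G protein subunit, fell by 0.94. Adults had more Hsf4, a heat shock transcription factor (log2 fold change 0.80), more Xdh, the xanthine dehydrogenase of purine breakdown (1.42), and more Ntn5, a netrin family member (1.69). Zbtb16, a transcription factor induced by glucocorticoids, rose by a log2 fold change of 0.58. The clock genes Per2, Per3, Hlf and Nr1d2 passed too (adjusted p = 0.00483, 0.0101, 0.0259 and 0.0367, edgeR), none of them in every fit that left out 1 library. A clock gene score was -2.31 to -1.12 in these adolescent libraries and -1.235 to 0.182 in the adult ones. Time of day at sampling was not tested for age and cannot be told apart from age by these genes.

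Of the 16 tested genes of immature neurons, 0 rose with age, 6 fell and 10 did not pass, and adjusted over the list alone 10 fell. Among them were Cd24a (log2 fold change -2.32), Dpysl3 (-0.58) and Sox4 (-0.59). The list as a whole was lower in adults (camera adjusted p = 3.51e-16), with an adjusted p = 0.00262 with an estimated correlation. Of 13 genes of newly formed oligodendrocytes, 0 rose, 5 fell and 8 did not pass, with 8 lower when adjusted over the list alone (camera adjusted p = 1.21e-11). Of 11 genes of oligodendrocyte precursors, 0 rose, 4 fell and 7 did not pass, with 7 lower when adjusted over the list alone (camera adjusted p = 3.25e-08). Both lists had an adjusted p = 0.00613 with an estimated correlation in all libraries and an adjusted p = 0.315 with an estimated correlation in the 35 deep ones. Gpr17, a receptor of differentiating oligodendrocytes, fell by 0.90 on the log2 scale and Pdgfra, the receptor that marks the precursors, by 0.34. The list of long nuclear RNAs was higher in adults (camera adjusted p = 3.92e-11), with 1 of 10 members past the threshold, 0 lower and 7 higher when adjusted over the list alone. Its adjusted p was 0.00536 with an estimated correlation in all libraries and 0.474 with an estimated correlation in the 35 deep ones.

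Genes of striatal neurons were lower in adults as a list (camera adjusted p = 2.16e-09, adjusted p = 0.1 with an estimated correlation), with 4 of 14 lower, 0 higher and 13 lower when adjusted over the list alone. In the 34 libraries this list had a camera adjusted p of 0.0356 and an adjusted p = 0.315 with an estimated correlation. Adora2a, an adenosine receptor of striatal neurons, had a log2 fold change of -3.18 (adjusted p = 0.0452) in all libraries and of -0.36 (adjusted p = 0.458) without adolescent water saline replicate 1. Genes of mature oligodendrocytes and myelin were lower as a list (camera adjusted p = 0.00341, adjusted p = 0.983 with an estimated correlation), with 0 of 24 past the threshold and 0 when adjusted over the list alone, and the direction turned in the 34 libraries. Fos, Fkbp5, Sgk1, Oprm1, Mbp and Cx3cr1, named in advance, did not pass for age, with adjusted p between 0.182 and 0.992.

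For age, 239 genes were higher and 269 lower in adults of 19348 tested, and 53 of the 508 had a predicted or clone-like name or no symbol. The count was 877 in the 34 libraries and 134 in DESeq2, and averaged over the 4 treatments it was 3599 (1692 higher, 1907 lower). With only the 2 compared groups in the fit it was 11, and in limma-voom with sample weights it was 1860. Without adult water saline replicate 1, 3 or 5 the count was 120, 105 or 188. Of the 67 named genes that passed, 23 passed in every fit that left out 1 library, while Pdgfra, Dpysl3 and Sox4 had an adjusted p of up to 0.108, 0.143 and 0.144 without adult water saline replicate 1, 3 and 5, in that order.

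**Figure D2:**
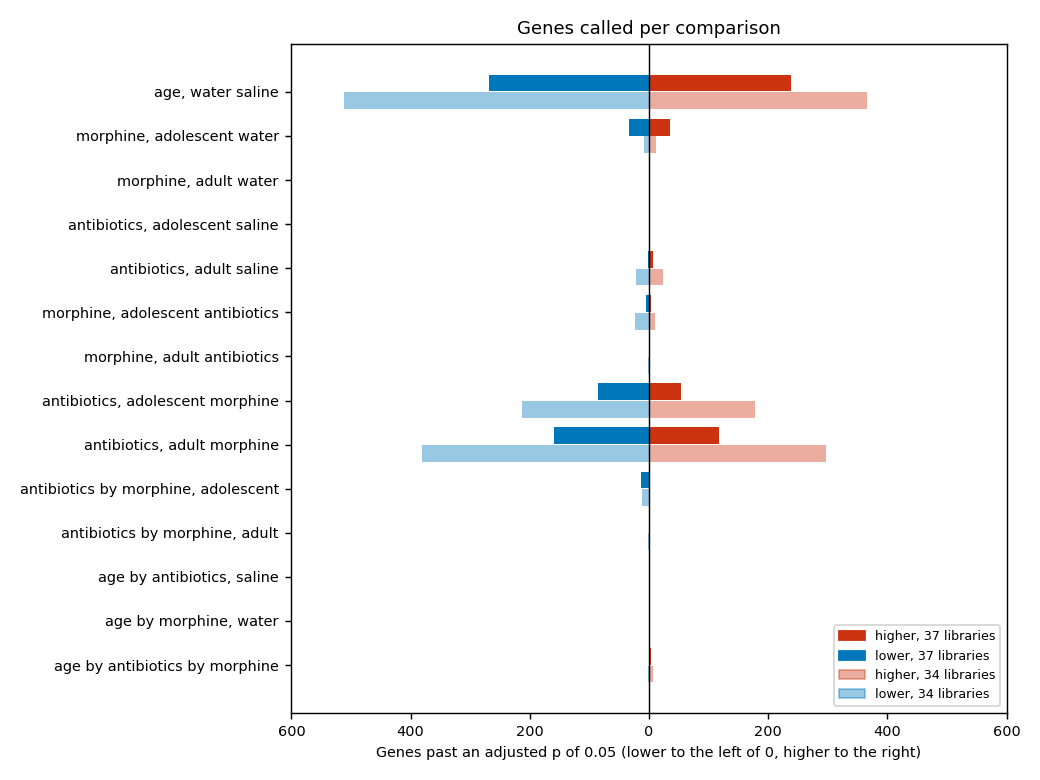
Number of genes past an adjusted p of 0.05 per comparison, for all 37 libraries (dark) and for 34 libraries (light). Genes lower in adults, with morphine or with antibiotics lie to the left of 0 and genes higher there to the right. For interactions, negative differences lie to the left and positive ones to the right. For age the bars show 269 lower and 239 higher genes, and for antibiotics in morphine-injected adults 159 lower and 118 higher genes.

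Morphine was then compared with saline in adolescents on water. Mthfd1l (ENSMUSG00000040675), an enzyme of mitochondrial folate metabolism, rose from 14.5 ± 1.29 CPM (SD, n = 5) to 20.4 ± 1.05 CPM (SD, n = 5), a log2 fold change of 0.50 (SE 0.07, adjusted p = 0.000122, edgeR). Per2 (ENSMUSG00000055866), a repressor of the circadian clock, rose from 39.1 ± 3 CPM to 59 ± 5.7 CPM (SD, n = 5 each), a log2 fold change of 0.59 (SE 0.08, adjusted p = 0.000122). Of 18 tested clock genes, 7 rose, 0 fell and 11 did not pass, while adjusted over the list alone 11 rose and 2 fell. Hlf (log2 fold change 0.41), Per1 (0.47) and Cry1 (0.47) were among them. A score of clock genes was -2.31 to -1.12 in the water saline libraries and 0.724 to 1.70 in the water morphine ones. In adolescents on antibiotics with saline it was -0.0611 to 0.6835. Time of day at sampling was not tested for this comparison and cannot be told apart from morphine by these genes. The list was higher with morphine (camera adjusted p = 7.15e-10), with an adjusted p = 0.129 with an estimated correlation in all libraries, an adjusted p = 0.0225 with an estimated correlation in the 35 deep ones and an adjusted p = 0.12 with an estimated correlation in the 34. St8sia2, which adds polysialic acid to neural adhesion molecules, fell by 1.22 on the log2 scale, Cacng4, an AMPA receptor accessory subunit, by 0.51 and Nos1, the neuronal nitric oxide synthase, by 0.50.

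In morphine-treated adolescents on water, immediate early genes were higher as a list (camera adjusted p = 1.37e-07, adjusted p = 0.262 with an estimated correlation), with 0 of 27 past the threshold and 6 higher when adjusted over the list alone. Genes of immature neurons were lower (camera adjusted p = 4.87e-07, adjusted p = 0.0892 with an estimated correlation), with 1 of 16 lower, Marcksl1 at a log2 fold change of -0.43, and 8 lower when adjusted over the list alone. Striatal genes were lower (camera adjusted p = 7.06e-13, adjusted p = 0.0892 with an estimated correlation), with 1 of 14 lower, Drd2, and 14 lower when adjusted over the list alone. Drd2 had an adjusted p of 0.0436 with all libraries and 0.724 without adolescent water saline replicate 1, and the striatal list had a camera adjusted p of 0.341 in the 34 libraries. Fkbp5, Fos, Sgk1, Oprm1, Mbp and Cx3cr1 did not pass, with adjusted p between 0.275 and 1.

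For morphine in adolescents on water, 35 genes were higher and 33 lower. The split into higher and lower genes was 16 and 6 in DESeq2, 9 and 2 in limma-voom and 25 and 10 with the islet-read term. Without the filter on low counts it was 19 and 24, and with DESeq2 size factors in edgeR 32 and 37. The count was 20 in the 34 libraries, 35 with the islet-read term, 22 in DESeq2, 43 without the filter on low counts, 11 in limma-voom and 1 with only the compared groups in the fit. It was 24, 42, 29, 197 or 239 without adolescent water saline replicate 1, 2, 3, 4 or 5, and 3, 11 or 8 without adolescent water morphine replicate 3, 4 or 5. Mthfd1l, Per2 and Hlf passed in every fit that left out 1 library, and the other 29 of the 32 named genes that passed did not.

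In adults on water, 0 genes passed for morphine in edgeR, with 504 genes at an unadjusted p under 0.05, 0 genes in DESeq2 and 3 in limma-voom. Mthfd1l had the smallest p and was at 15.6 ± 1.08 CPM (SD, n = 3) with saline and at 20.5 ± 0.878 CPM (SD, n = 5) with morphine (log2 fold change 0.39, SE 0.08, adjusted p = 0.444, edgeR). Trib1, a pseudokinase, had a log2 fold change of 0.71 and Spry4, an inhibitor of growth factor receptor signalling, one of 0.51, both with an adjusted p of 1. Immediate early genes were higher as a list (camera adjusted p = 0.000152, adjusted p = 0.999 with an estimated correlation), with 0 of 27 past the threshold and 0 when adjusted over the list alone. The difference between the ages in the morphine effect on water gave 0 genes in edgeR, with 1236 at an unadjusted p under 0.05, 0 genes in DESeq2 and 1 in limma-voom.

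In adolescents on antibiotics, morphine was compared with saline in the same way. Stk40 (ENSMUSG00000042608), a serine/threonine kinase-like protein, fell from 41.8 ± 1.19 CPM (SD, n = 3) to 29.4 ± 2.35 CPM (SD, n = 5), a log2 fold change of -0.51 (SE 0.08, adjusted p = 0.00517, edgeR). The transcription factor Klf10 fell by 0.80 on the log2 scale, Spry4 by 0.73, Nab2, a corepressor of EGR transcription factors, by 0.42, and Fabp7, a fatty acid binding protein of astrocytes and progenitors, by 0.92. Mthfd1l rose by a log2 fold change of 0.47, the clock repressor Cry1 by 0.56, Zbtb16 by 0.50 and Lyst, a lysosomal trafficking regulator, by 0.41. Immediate early genes were lower as a list (camera adjusted p = 3.86e-08, adjusted p = 0.536 with an estimated correlation), with 0 of 27 past the threshold and 15 lower when adjusted over the list alone. Fos itself had a log2 fold change of -1.03 (adjusted p = 0.562).

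For morphine in adolescents on antibiotics, 4 genes were higher and 5 lower, and with DESeq2 size factors in edgeR the split was 4 higher and 8 lower. The count was 33 in the 34 libraries, 25 in DESeq2, 115 in limma-voom and 104 with only the compared groups in the fit. It was 2 or 0 without adolescent antibiotics saline replicate 1 or 5, and 5 or 2 without adolescent antibiotics morphine replicate 1 or 2, and none of the 9 named genes passed in every such fit. In adults on antibiotics, 0 genes passed for morphine in edgeR, with 1393 at an unadjusted p under 0.05, 7 genes in DESeq2, 1 in limma-voom and 3 in the 34 libraries. Without adult antibiotics saline replicate 5 the count was 1 and without adult antibiotics morphine replicate 3 it was 11. Cry1 (log2 fold change 0.43, adjusted p = 0.145) and Mthfd1l (0.33, adjusted p = 0.171) were again among the smallest p values. As a list, immediate early genes were higher there (camera adjusted p = 2.84e-10, adjusted p = 0.578 with an estimated correlation), with 0 of 27 past the threshold and 2 higher when adjusted over the list alone.

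Antibiotics were compared with water in mice given saline. In adolescents 1 gene passed, Amn (ENSMUSG00000021278), which encodes the amnionless subunit of the vitamin B12 receptor. It was at 10.2 ± 1.79 CPM (SD, n = 3) with antibiotics and at 4.95 ± 1.29 CPM (SD, n = 5) with water, a log2 fold change of 1.04 (SE 0.19, adjusted p = 0.0402, edgeR). Fkbp5, a glucocorticoid-induced chaperone, had a log2 fold change of 0.44 (adjusted p = 0.393), and Igfbp4, which binds insulin-like growth factors, one of 0.40 (adjusted p = 0.0541). Immediate early genes were higher as a list (camera adjusted p = 0.0068, adjusted p = 0.983 with an estimated correlation), with 0 of 27 past the threshold and 5 higher when adjusted over the list alone, and its direction turned in fry (adjusted p = 0.496). Of the 47 lists 2 passed camera here, and 17 did in the 35 deep libraries. DESeq2 called 19 genes, limma-voom 17, the fit without a filter on low counts 3, the 35 deep libraries 2, and the 34 libraries and the fit of the compared groups 0, with 1782 at an unadjusted p under 0.05 in edgeR. The count was 0 without adolescent water saline replicate 1, 2 or 3 or adolescent antibiotics saline replicate 2 or 5, 2 without adolescent antibiotics saline replicate 3, and 5 or 15 without adolescent water saline replicate 4 or 5.

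Antibiotics were compared with water in saline-injected adults too. Cirbp (ENSMUSG00000045193), a cold-inducible RNA-binding protein, was at 52.4 ± 2.71 CPM (SD, n = 3) with water and at 73.5 ± 7.9 CPM (SD, n = 5) with antibiotics, a log2 fold change of 0.49 (SE 0.08, adjusted p = 0.00663, edgeR). Rbm3 rose by a log2 fold change of 0.45 and Rbm3os, which overlaps it on the other strand, by 0.54, and the strand setting of the counting is not given in the sources used here, so which of the pair the reads came from is uncertain. Zfas1, a host gene of small nucleolar RNAs, rose by 0.67 and Plin4, a lipid droplet protein, by 1.83. Etnppl, an astrocyte enzyme that breaks down phosphoethanolamine, rose from 18.8 ± 3.51 CPM (SD, n = 3) to 44.9 ± 12.7 CPM (SD, n = 5). Slco1c1, a thyroid hormone transporter of the blood-brain barrier, fell by 0.42 on the log2 scale. Fkbp5 had a log2 fold change of 0.81 (adjusted p = 0.091).

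Glucocorticoid-responsive genes were higher as a list in saline-injected adults on antibiotics (camera adjusted p = 6.54e-11, adjusted p = 0.375 with an estimated correlation), with 1 of 25 higher, Plin4, and 13 higher when adjusted over the list alone. Endoplasmic reticulum stress genes were lower (camera adjusted p = 9.24e-05, adjusted p = 0.375 with an estimated correlation), with 0 of 19 past the threshold and 9 lower when adjusted over the list alone. In the 35 deep libraries the latter list had an adjusted p = 0.0178 with an estimated correlation. In total 6 genes were higher and 1 lower, and with DESeq2 size factors the split was 6 higher and 2 lower. The count was 44 in the 34 libraries, 116 in limma-voom, 1 in DESeq2 and 0 with only the compared groups in the fit, and edgeR gave 1463 genes at an unadjusted p under 0.05 with all groups. It was 1, 1 or 3 without adult water saline replicate 1, 3 or 5, and 3, 14, 3 or 4 without adult antibiotics saline replicate 2, 3, 4 or 5. Zfas1 passed in every fit that left out 1 library, and the other 6 genes did not.

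In morphine-injected adolescents, antibiotics raised Cirbp from 54.5 ± 4.37 CPM to 78.7 ± 4.45 CPM (SD, n = 5 each), a log2 fold change of 0.53 (SE 0.07, adjusted p = 8.49e-05, edgeR). Etnppl (log2 fold change 1.00), Zfas1 (0.43), Mir9-3hg, the host transcript of a neural microRNA (0.46), and Fkbp5 (0.70) also rose. Spry4 (ENSMUSG00000024427) fell from 19.6 ± 2.42 CPM to 11.1 ± 0.775 CPM (SD, n = 5 each), a log2 fold change of -0.82 (SE 0.12, adjusted p = 0.00031). Stk40 fell by 0.47 on the log2 scale, Apln, the peptide apelin, by 0.94, P4ha1, a collagen prolyl hydroxylase, by 0.47 and the growth factor Bdnf by 0.56. Of 10 fits that left out 1 library each, P4ha1 passed in 10 and Bdnf in 1.

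Of 27 immediate early genes in morphine-injected adolescents, 0 rose with antibiotics, 4 fell and 23 did not pass, while 17 were lower when adjusted over the list alone. Those past the threshold were Dusp6 (log2 fold change -0.67), Sik1 (-0.53), Dusp5 (-0.59) and Nr4a1 (-0.72). Of 10 fits that left out 1 library each, Dusp6 passed in 10, Sik1 and Dusp5 in 2 and Nr4a1 in 1. The list was lower (camera adjusted p = 1.62e-29), with an adjusted p = 0.00459 with an estimated correlation in all libraries and an adjusted p = 0.149 with an estimated correlation in the 35 deep ones. Fos had a log2 fold change of -0.77 (adjusted p = 0.353). Of 19 endoplasmic reticulum stress genes, 0 rose, 6 fell and 13 did not pass, while 11 were lower when adjusted over the list alone. Hspa5 (ENSMUSG00000026864), the main chaperone of that compartment, fell from 190 ± 6.63 CPM to 146 ± 9.78 CPM (SD, n = 5 each), a log2 fold change of -0.38 (SE 0.07, adjusted p = 0.00308, edgeR). Sdf2l1 fell by 0.69 on the log2 scale, and the protein disulfide isomerases Pdia4 and Pdia6 by 0.49 and 0.31. The list was lower (camera adjusted p = 3.83e-07), with an adjusted p = 0.0682 with an estimated correlation in all libraries and an adjusted p = 0.00405 with an estimated correlation in the 35 deep ones.

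Heat shock genes were lower as a list in the same mice (camera adjusted p = 1.42e-05, adjusted p = 0.675 with an estimated correlation), with 2 of 17 lower, Hsph1 and Chordc1, 0 higher and 4 lower when adjusted over the list alone. Microglial genes were lower (camera adjusted p = 0.000349, adjusted p = 0.438 with an estimated correlation), with 1 of 20 lower, Fcrls, and 4 lower when adjusted over the list alone. The mitochondrial share of counts was 4.89% to 5.08% in the 5 adolescent water morphine libraries and 4.19% to 4.81% in the 5 adolescent antibiotics morphine libraries. In total 54 genes were higher and 86 lower with antibiotics in morphine-injected adolescents. The count was 390 in the 34 libraries, 214 in the 35 deep libraries, 378 with only the compared groups in the fit, 681 in limma-voom and 12 in DESeq2. It was 76 or 88 without adolescent water morphine replicate 2 or 5, and 51, 89 or 84 without adolescent antibiotics morphine replicate 1, 2 or 5. Of the 43 named genes that passed, 24 passed in every fit that left out 1 library, Cirbp, Etnppl, Spry4, Stk40, Apln, Hspa5, Sdf2l1, Pdia4, Pdia6, Hsph1, Chordc1 and Dusp6 among them.

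In morphine-injected adults, antibiotics raised Cirbp from 50.6 ± 4.92 CPM (SD, n = 5) to 84.4 ± 8.88 CPM (SD, n = 4), a log2 fold change of 0.74 (SE 0.08, adjusted p = 8.53e-08, edgeR). Etnppl (ENSMUSG00000019232) rose from 17.6 ± 2.39 CPM (SD, n = 5) to 56 ± 10.2 CPM (SD, n = 4), a log2 fold change of 1.66 (SE 0.18, adjusted p = 3.29e-06). Plin4 (log2 fold change 2.06), Fkbp5 (1.00), Rbm3 (0.56) and Mir9-3hg (0.57) rose too. Fabp7 fell by 1.22 on the log2 scale, Akt2, a kinase of insulin signalling, by 0.54, Grm3 and Grm7, metabotropic glutamate receptors, by 0.53 and 0.41, and Apln by 0.85. Tubb2b and Tubb3, neuronal tubulins, fell by 0.79 and 0.32.

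Of 20 microglial genes in morphine-injected adults, 0 rose with antibiotics, 7 fell and 13 did not pass, while 13 were lower when adjusted over the list alone. Itgam (log2 fold change -0.76), Fcrls (-0.60), Tmem119 (-0.38) and the fractalkine receptor Cx3cr1 (-0.32) were among them. Without adult antibiotics morphine replicate 2 these 4 did not pass, with adjusted p of 0.0681, 0.0707, 0.102 and 0.0981. The list was lower (camera adjusted p = 0.00304), with an adjusted p = 0.965 with an estimated correlation. Of 23 cholesterol synthesis genes, 0 rose, 4 fell and 19 did not pass, while 10 were lower when adjusted over the list alone (camera adjusted p = 0.00286, adjusted p = 0.965 with an estimated correlation). Srebf2 (log2 fold change -0.20), Hmgcs1 (-0.47) and Msmo1 (-0.42) were among those that fell, with adjusted p of 0.135, 0.154 and 0.212 without adult antibiotics morphine replicate 2. Of 25 glucocorticoid-responsive genes, 4 rose, 0 fell and 21 did not pass, while 5 were higher when adjusted over the list alone (camera adjusted p = 0.00197, adjusted p = 0.965 with an estimated correlation). Heat shock genes were lower as a list (camera adjusted p = 0.0143, adjusted p = 0.965 with an estimated correlation), with 2 of 17 lower, 0 higher and 3 lower when adjusted over the list alone. Endoplasmic reticulum stress genes did not pass as a list (camera adjusted p = 0.323), with 2 of 19 lower, Calr and Pdia6, and 5 lower when adjusted over the list alone.

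For antibiotics in morphine-injected adults, 118 genes were higher and 159 lower. The count was 678 in the 34 libraries, 696 in limma-voom and 50 in DESeq2. It was 175, 146, 166 or 127 without adult water morphine replicate 1, 2, 3 or 4, and 126 or 60 without adult antibiotics morphine replicate 1 or 2. Of the 54 named genes that passed, 22 passed in every fit that left out 1 library, Cirbp, Etnppl, Rbm3, Plin4, Fkbp5, Mir9-3hg, Fabp7, Akt2, Grm3, Grm7, Apln and Tubb2b among them.

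**Figure D3:**
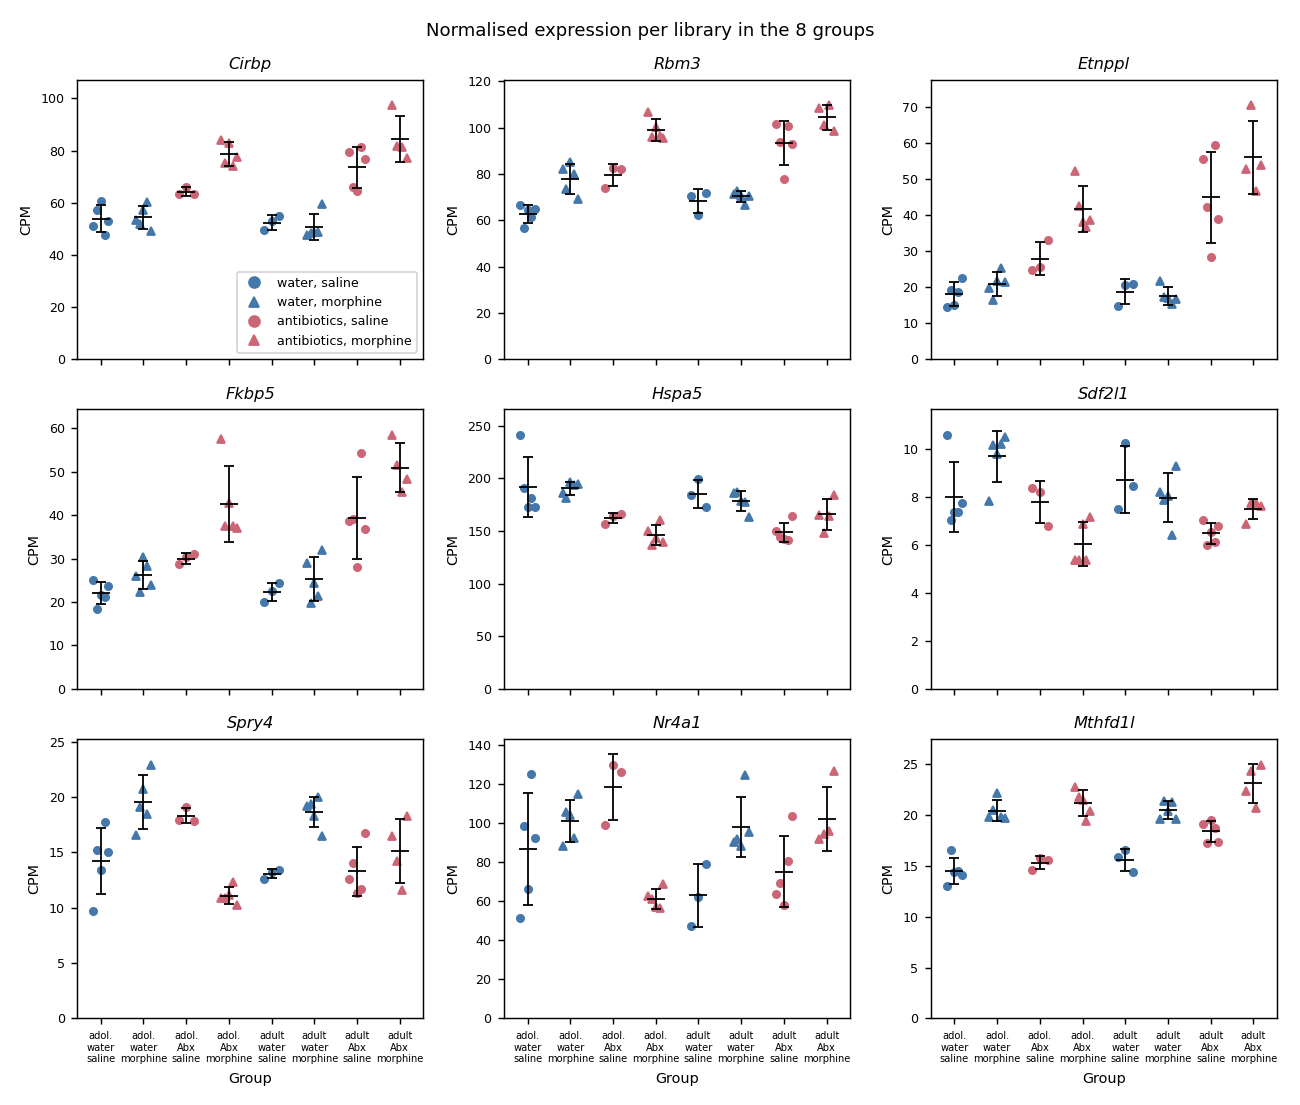
Normalised expression in CPM on linear axes from 0 for 9 genes in the 35 libraries with over 1000000 counts, with the 8 groups on the horizontal axis, 1 point per library and black bars for the mean and SD. Cirbp, Rbm3, Etnppl and Fkbp5 had their highest group means with antibiotics and morphine, Cirbp at 84.4 CPM in adults, and Spry4 was at 11.1 CPM in adolescents given both.

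The antibiotic effects in mice given morphine were compared between the ages, which share no library. The calls at both ages held 21 genes higher at both ages, where independent lists of the same lengths would share 0.329, and 29 genes lower at both ages, where they would share 0.707. The number of genes called in opposite directions was 0. Of the 7 genes called in saline-injected adults, 6 were called higher and 1 lower in morphine-injected adults as well. Across all 19348 genes, which are not independent replicates, the log2 fold changes of the 2 ages with morphine had a Spearman correlation of 0.318.

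Whether antibiotics altered the response to morphine was tested as a difference of differences. In adolescents 0 genes were higher and 13 lower for this interaction, so that the morphine effect lay below that seen on water. Spry4 had the smallest p, with a difference in log2 fold change of -1.20 (SE 0.18, adjusted p = 0.00117, edgeR). Stk40 (-0.70), Per1 (-0.75), Klf10 (-1.09), Dusp5 (-1.25), a phosphatase of ERK kinases, and Nab2 (-0.60) followed. Per1 was at 101 ± 12.1 CPM with water and saline, 139 ± 10.1 CPM with water and morphine (SD, n = 5 each), 140 ± 14.1 CPM with antibiotics and saline (SD, n = 3) and 115 ± 13.5 CPM with antibiotics and morphine (SD, n = 5). Adolescents on water with saline also had the lowest clock scores of these groups, so time of day was not separated from treatment for Per1. Immediate early genes were lower as a list for this interaction (camera adjusted p = 2.54e-13, adjusted p = 0.237 with an estimated correlation), with 0 of 27 higher, 2 lower and 14 lower when adjusted over the list alone. The count was 1 in DESeq2 and 21 in limma-voom. It was 8 or 22 without adolescent water saline replicate 3 or 4, 7 without adolescent water morphine replicate 5, and 5 or 6 without adolescent antibiotics saline replicate 2 or 5. Spry4, Stk40, Per1, Klf10 and Dusp5 passed in every fit that left out 1 library, and Nab2 had an adjusted p of 0.064 without adolescent antibiotics saline replicate 2.

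In adults the same interaction gave 0 genes in edgeR, with 675 at an unadjusted p under 0.05, 0 genes in DESeq2 and 1 in limma-voom, in the 35 deep libraries and in the 34 libraries. The difference between the ages in the antibiotic effect with saline gave 0 genes in edgeR, with 979 at an unadjusted p under 0.05, and 0 genes in DESeq2 and limma-voom. The difference between the ages in the interaction gave 3 genes, all higher, of which Midn, a nuclear protein involved in protein degradation (difference 0.96, SE 0.18), and Nab2 (0.81, SE 0.15) had an adjusted p of 0.0497 in edgeR. For that difference, immediate early genes were higher as a list (camera adjusted p = 4.33e-17, adjusted p = 0.0425 with an estimated correlation), with 0 of 27 past the threshold and 13 higher when adjusted over the list alone, and the 35 deep libraries gave an adjusted p = 0.203 with an estimated correlation. The 3 genes became 0 with the islet-read term, 10 in DESeq2, 9 in limma-voom, 7 in the 34 libraries, 6 with DESeq2 size factors and 5 in the 35 deep libraries. Leaving out 1 library took the count of 3 to between 0 and 7, as listed with the processing alternatives.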

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

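The tests of a neighbouring brain region, of depth and of a wrong age label as the cause of striatal transcripts were chosen only after the result was seen, and so were the differences between the ages in the morphine effect on antibiotics. A library was called far from its group when its gap to the nearest other library took an unusually large share of the group's range (Dixon's test at 95%). Of 72 groups of values tested, 13 held such a library, where chance gives about 1 in 20, or 3.6.

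Adult antibiotics morphine replicate 4 held 58764 counts, against 13373978 to 17467680 in the others of its group. The 10 highest genes took 7.18% of the counts in adolescent antibiotics morphine replicate 2, against 8.33% to 8.47%, and 5.5% in adult antibiotics saline replicate 2, against 8.53% to 9.01%. Mbp was at 2750 CPM in adolescent water morphine replicate 5 (801 to 1260 CPM in the others), at 1694 CPM in adult water morphine replicate 5 (741 to 872 CPM) and at 2722 CPM in adult antibiotics saline replicate 5 (847 to 1375 CPM). Ttr, a transcript of the choroid plexus, was at 15.8 CPM in adolescent water morphine replicate 5 (0.0814 to 0.433 CPM in the others). It was at 33.9 CPM in adult antibiotics saline replicate 4 (0 to 0.124 CPM). In adult antibiotics morphine replicate 1 it was at 0.286 CPM, against 0 CPM in the other deep libraries of that group. The near-empty adult antibiotics morphine replicate 4, where Ttr was higher than in replicate 1, was left out of this comparison. Cirbp was at 59.3 CPM in adult water morphine replicate 5, against 47.6 to 48.8 CPM.

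Adolescent water saline replicate 1 had Drd2 at 55.6 CPM (0.679 to 2.51 CPM in the others), Mbp at 8916 CPM (526 to 1224 CPM) and Slc17a7 at 1222 CPM (1740 to 1890 CPM). Greater depth is argued against as the cause, since with TMM scaling Drd2 was at 53.3 CPM here and at 0.959 CPM in the deepest library of all. The library was the highest of the 35 for 14 of the 14 tested striatal genes and for 23 of 24 myelin genes, and the lowest for Slc17a7, so striatal tissue and white matter in the dissected piece are a candidate explanation. A wrong age label is argued against as the cause of these transcripts, since the library lay above every adult library for 14 of 14 striatal genes, while the label itself stays open, since a score of 50 genes higher and 50 genes lower in adults was -2.15 here, -2.64 to -2.21 in the other adolescent libraries and -1.8 to -1.38 in the adult ones, outside both ranges. No biological explanation was tested.

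The interaction of antibiotics and morphine in adolescents differed from 0 for Spry4 (-1.20), Stk40 (-0.70), Per1 (-0.75), Klf10 (-1.09), Dusp5 (-1.25) and Nab2 (-0.60). The interaction itself differed between the ages for Nab2 (0.81) and Midn (0.96), which passed in 14 and 11 of 37 fits that left out 1 library. In mice on antibiotics, the morphine effect differed between the ages for Nab2 (0.65), Stk40 (0.65) and Zbtb16 (-0.75). Without adolescent antibiotics saline replicate 5 the adjusted p was 0.0991 for Stk40 and 0.138 for Zbtb16, while Nab2 passed for this difference in every fit that left out 1 library.

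Regrouping the same libraries gave the following. For antibiotics in morphine-injected adolescents the real groups gave 140 genes and the highest other split 0, for morphine in adolescents on antibiotics 9 and 5, for antibiotics in saline-injected adults 7 and 5, for antibiotics in morphine-injected adults 277 and 237, and for the interaction in adolescents 13 and 7. In each of these the real split alone reached its count (1 of 60, 60, 56, 60 and 40 splits). That is the smallest share such splits can give, and many contrasts were regrouped, so it argues against chance without excluding it. For the interaction the splits exchanged water and antibiotics within each injection. They thus also removed any antibiotic effect and do not test the interaction alone. The split with 237 genes differed from the real one in 2 of its 10 libraries. For morphine in adolescents on water 2 of 60 splits reached 68 genes, the real one included. The highest other split gave 232 and differed from the real one in 4 of its 10 libraries. This points to a structure of the samples, so chance is not excluded. For age in water-drinking, saline-injected mice 4 of 56 splits reached 508 genes and the highest other gave 1033, so this test does not exclude chance. The split with 1033 genes differed from the real one in 6 of its 8 libraries. It set adolescents alone against all adults with the remaining adolescents, so it still carried age. Averaged over the 4 treatments, age gave 3599 genes, and that average was not regrouped. For antibiotics in saline-injected adolescents 17 of 60 splits reached 1 gene and the highest other gave 706, so chance is not excluded and a structure of the samples is again seen. The split with 706 genes differed from the real one in 6 of its 9 libraries. For the difference between the ages in the interaction 2 of 40 splits reached 3 genes (highest other 77). For that in the morphine effect on antibiotics 2 of 40 reached 5 (highest other 109), so chance is not excluded in either. These splits exchanged the ages among mice of the same treatment. Uneven ones thus still carried age, so they do not test these differences alone. The highest splits do not by themselves show a structure of the samples.

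Comparisons with 0 genes in edgeR are reached by every split. The highest other split gave 1 gene for morphine in adults on water (56 of 56), 113 for morphine in adults on antibiotics (60 of 60), 189 for the interaction in adults (40 of 40), 86 for age by antibiotics with saline (40 of 40), 1 for age by morphine on water (40 of 40) and 9 for age by antibiotics with morphine (40 of 40). The counts at an unadjusted p under 0.05 were 504, 1393, 675, 979, 1236 and 741 in that order, and DESeq2 gave 0, 7, 0, 0, 0 and 0 genes. The split with 113 genes, where the real groups gave 0, points to a structure of the samples. For the interaction in adults the splits exchanged water and antibiotics within each injection. For age by antibiotics they exchanged the ages within water and within antibiotics. Uneven splits of these kinds still carry an antibiotic or age effect. The 189, 86 and 9 genes therefore do not by themselves show a structure of the samples.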

How the results depend on the processing

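The fits of 35 and 34 libraries, the islet-read term, and the averages and interactions added to the plan were chosen only after the data were seen. Of 352 results of named genes past the threshold, 345 stayed past it with DESeq2 size factors, 284 without a filter, 317 with the replicate block, 118 in DESeq2, 318 in limma-voom, 341 in the 35 libraries, 317 in the 34, 321 with the islet-read term and 165 in every fit with 1 library left out, and 102 of 219 with only the compared groups, and 0 changed sign. No clear pairing of the libraries by replicate number was seen. Residuals of the same number had a mean correlation of 0.0261 (-0.448 to 0.642 over 108 pairs) and those of different numbers -0.00122. A weak or partial pairing is not excluded by these means. The cause was not tested for the changes below. Depth limits the 2 near-empty libraries, and leaving out both moved several counts below.

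With only the compared groups in the fit, the number of genes was 11 for age, 1 for morphine in adolescents on water, 0 for antibiotics in adolescents and in adults with saline, 104 for morphine in adolescents on antibiotics and 378 for antibiotics in adolescents with morphine. DESeq2 gave 134, 22, 19, 1, 25, 7, 12 and 50 for age, morphine in adolescents on water, antibiotics in adolescents and adults with saline, morphine in adolescents and adults on antibiotics, and antibiotics in adolescents and adults with morphine, and 1 for the adolescent interaction, 10 for its difference between ages, 29 for age by morphine on antibiotics, 257 for averaged antibiotics and 3 for averaged morphine. limma-voom gave 1860, 11, 3, 17, 116, 115, 1, 681 and 696 for age, morphine in adolescents and adults on water, antibiotics in adolescents and adults with saline, morphine in adolescents and adults on antibiotics, and antibiotics in adolescents and adults with morphine. It gave 21, 1, 1, 9, 1 and 19 for the interaction in adolescents and adults, age by morphine on water, the interaction's difference between ages, age by antibiotics with morphine and age by morphine on antibiotics, and 3274 and 342 for averaged antibiotics and morphine.

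The 34 libraries gave 877, 20, 0, 44, 33, 3, 390 and 678 for age, morphine in adolescents on water, antibiotics in adolescents and adults with saline, morphine in adolescents and adults on antibiotics, and antibiotics in adolescents and adults with morphine. They gave 1, 7, 1 and 11 for the adult interaction, the interaction's difference between ages, age by antibiotics with morphine and age by morphine on antibiotics, and 2510 and 251 for averaged antibiotics and morphine. The 35 libraries gave 2 for antibiotics in adolescents with saline, 214 for antibiotics in adolescents with morphine, 1 for the adult interaction, 5 for its difference between ages, 1 for age by antibiotics with morphine and 61 for averaged morphine. Without a filter the number was 43 for morphine in adolescents on water, 3 for antibiotics in adolescents with saline and 8 for age by morphine on antibiotics. With DESeq2 size factors it was 6 for the interaction's difference between ages, 8 for age by morphine on antibiotics and 42 for averaged morphine. The replicate block gave 24 for morphine in adolescents on antibiotics, 22 for the adolescent interaction, 1 for age by antibiotics with saline, 9 for age by morphine on antibiotics and 34 for averaged morphine. The islet-read term gave 35 for morphine in adolescents on water and 0 for the interaction's difference between ages. Age averaged over the 4 treatments gave 3599.

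Over the 9 contrasts and 5 interactions set in advance, 118 list results passed camera, and 7 did with an estimated correlation, 0 in fry, and 5 and 3 with an estimated correlation in the 35 and 34 libraries. In the 35 libraries the lists passing camera went from 2 to 17 for antibiotics in adolescents with saline, from 5 to 16 for morphine in adolescents on antibiotics and from 3 to 14 for the adolescent interaction. List directions turned for age in myelin genes in the 34 libraries (adjusted p = 0.0522, and 0.901 with an estimated correlation). For morphine in adolescents on water they turned in the 34 libraries for newly formed oligodendrocytes (0.926, and 0.976 estimated), upper cortical layers (0.758, and 0.976 estimated) and cell division (0.614, and 0.934 estimated). In fry they turned for immediate early genes with antibiotics in saline-injected adolescents (0.496) and in age by antibiotics with saline (0.700), and for microglia (0.814), astrocytes (0.451) and glutamatergic neurons (0.537) with morphine in adolescents on antibiotics. The last list also turned in the 35 libraries (0.928, and 0.97 estimated).

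Leaving out 1 library gave 105 to 730 genes for age, 3 to 239 for morphine in adolescents on water, 0 to 15 for antibiotics in adolescents with saline, 1 to 14 in adults with saline, 0 to 10 and 0 to 11 for morphine in adolescents and adults on antibiotics, 51 to 138 and 60 to 391 for antibiotics in adolescents and adults with morphine, 5 to 22 for the adolescent interaction, 0 to 1 for age by antibiotics with morphine, where adult antibiotics morphine replicate 1 gave the 1, 1175 to 2246 for averaged antibiotics and 0 to 0 for morphine in adults on water, the adult interaction, age by antibiotics with saline and age by morphine on water. For averaged morphine it gave 5 to 163, with 163 and 34 without adolescent water saline replicate 1 and 5, 12 and 5 without adult water saline replicate 1 and 3, 14 and 34 without adolescent antibiotics saline replicate 1 and 3, and 64 without adult antibiotics morphine replicate 3. For age by morphine on antibiotics it gave 1 to 13, with 2 without adolescent antibiotics saline replicate 5, 1, 3 and 1 without adolescent antibiotics morphine replicate 1, 2 and 3, 2, 3 and 13 without adult antibiotics saline replicate 2, 3 and 5, and 3 without adult antibiotics morphine replicate 1.

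For the interaction's difference between ages it gave 0 to 7. The number was 0 without adolescent water saline replicate 3 or 5, adolescent water morphine replicate 2, 3, 4 or 5, adult water saline replicate 3 or 5, adult water morphine replicate 1, 2, 3 or 5, adolescent antibiotics saline replicate 2 or 5, adolescent antibiotics morphine replicate 2, 3 or 4, adult antibiotics saline replicate 2, 3 or 4, or adult antibiotics morphine replicate 1 or 5. It was 7 without adolescent water saline replicate 1, 1 without adult antibiotics saline replicate 5, and 5 without adolescent water saline replicate 4, adult water saline replicate 1, adult water morphine replicate 4 or adolescent antibiotics morphine replicate 5.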

Other observations

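The averages over strata, the further interactions and the tests of islet reads were chosen only after the data were seen. Averaged over both ages and both injections, antibiotics raised 778 genes and lowered 879 in edgeR, 1657 in all, against 257 in DESeq2, 2510 in the 34 libraries and 3274 in limma-voom. Cirbp rose by a log2 fold change of 0.51 (SE 0.04, adjusted p = 1.73e-11), Rbm3 by 0.42, Etnppl by 1.14 and Fkbp5 by 0.74, and Cirbp lay above the mean of the matching water group in 17 of 17 libraries. Fabp7 fell by 0.80 on the log2 scale, Hspa5 by 0.26 and Cx3cr1 by 0.24. Of 19 endoplasmic reticulum stress genes 0 rose and 12 fell, 13 when adjusted over the list alone, while the list had a camera adjusted p of 0.115 and an adjusted p = 0.981 with an estimated correlation in all libraries, and an adjusted p = 0.00941 with an estimated correlation in the 35 deep ones. Of 17 heat shock genes 0 rose and 4 fell, 5 when adjusted over the list alone (camera adjusted p = 0.00208, adjusted p = 0.981 with an estimated correlation). Of 23 cholesterol synthesis genes 0 rose and 12 fell, 14 when adjusted over the list alone (camera adjusted p = 3.21e-05, adjusted p = 0.981 with an estimated correlation). Of 25 glucocorticoid-responsive genes 10 rose and 0 fell, 16 higher when adjusted over the list alone (camera adjusted p = 5.13e-06, adjusted p = 0.981 with an estimated correlation). The real groups gave 1657 genes and the highest of the other splits 1 (1 of 40 splits as large), which argues against chance. A share of 1 in 40 is the smallest these splits can give.

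Averaged in the same way, morphine raised 7 genes and lowered 15 in edgeR. Mthfd1l rose by a log2 fold change of 0.42 (adjusted p = 1.42e-09), Cry1 by 0.45 and Per2 by 0.28, and Fabp7 fell by 0.51 on the log2 scale. These 4 genes and Akt2 passed in every fit that left out 1 library, and the other 16 of the 21 named genes did not. The count of 22 was 251 in the 34 libraries, 61 in the 35 deep ones, 342 in limma-voom and 3 in DESeq2. It was 163 or 34 without adolescent water saline replicate 1 or 5, 12 or 5 without adult water saline replicate 1 or 3, 14 or 34 without adolescent antibiotics saline replicate 1 or 3, and 64 without adult antibiotics morphine replicate 3. The real groups gave 22 genes and the highest of the other splits 2 (1 of 40 splits as large), which argues against chance without excluding it. A share of 1 in 40 is the smallest these splits can give.

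In morphine-injected mice the antibiotic effect differed between the ages for 0 genes in edgeR, with 741 at an unadjusted p under 0.05, 0 in DESeq2 and 1 in limma-voom. Immediate early genes were higher as a list for that difference (camera adjusted p = 2.43e-22, adjusted p = 0.023 with an estimated correlation, and adjusted p = 0.134 and 0.122 with an estimated correlation in the 35 and 34 libraries), with 0 of 27 past the threshold and 8 higher when adjusted over the list alone. For the difference between the ages in the morphine effect on antibiotics the same list was higher (camera adjusted p = 7.67e-18, adjusted p = 0.07 with an estimated correlation, and adjusted p = 0.0221 and 0.0131 with an estimated correlation in the 35 and 34 libraries), with 0 of 27 past the threshold and 14 higher when adjusted over the list alone.

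The pattern weighed here is Cirbp and Rbm3 higher and some genes of the endoplasmic reticulum stress and heat shock lists lower with antibiotics. In the 35 libraries, 20 of its 38 genes passed for the averaged antibiotic effect, and 20 still passed with a term for islet reads. Islet reads did not differ between antibiotics and water in adolescents (Fisher exact p = 0.63) and were absent in adults. This term could therefore hardly remove an antibiotic effect. A batch that goes with antibiotics was not tested, and Fabp1 reads in adults were not used as a term. With a score of clock genes 17 passed, which argues against time of day as the whole cause. With marker scores of 6 cell types 9 passed, so a change in the mix of cell types may account for part of the chaperone change. Hspa5 went from -0.26 (SE 0.04) to -0.17 (SE 0.04), while Cirbp went from 0.51 (SE 0.04) to 0.49 (SE 0.05). Some markers in these scores, such as Cx3cr1 and Fcrls, were themselves called for antibiotics. The scores thus cannot tell a change in cell numbers from a change of expression within cells. Part of the loss of calls may also come from the added terms raising the error. Of all genes, 1975 passed in these 35 libraries without a term and 593 with the marker scores. With the clock score 1305 passed and with the islet-read term 1886. A change in the mix of cell types may thus account for part of the wider antibiotic effect as well, and so may a difference in time of day. An effect of the antibiotics themselves stays open and was not tested apart from these explanations.

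Islet hormone transcripts were seen in 7 of 18 deep adolescent libraries and 0 of 17 deep adult ones, with at most 5 counts of Ins2 elsewhere. Their presence differed between the ages (Fisher exact p = 0.0076). Fabp1 reads, at most 12 counts, were absent from every adolescent library and present in all adult water libraries and in some adult antibiotics ones. A batch that goes with age cannot be told apart from age in the 508, or averaged 3599, genes called for age. Expression by adolescent cortex is argued against by 11 deep adolescent libraries with 10 or fewer Ins2 counts, and a response to treatment by 489 counts of Ins2 in an adolescent water saline library. All 7 libraries also held Ins1, Gcg and Iapp, so reads or RNA from islet samples handled alongside are a candidate explanation. No biological explanation was tested beyond these.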
